A study of Mus musculus with 48 samples.

How the data were processed

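Livers of wild-type C57BL/6 mice and of mice labelled as knockouts of the small heterodimer partner SHP, encoded by Nr0b2, were profiled by RNA sequencing. Per the labels' protocols, mice received a liquid diet with 5% ethanol or with maltose for 10 days, then at 9am on day 11 a binge of 5 g/kg ethanol or 9 g/kg maltose dextrin. Livers were taken at 6pm, midnight (12am), 6am and noon (12pm). The 2 genotypes, 2 treatments and 4 times made 16 groups of 3 mice, 48 libraries in all, and the series' design text describes the mice of a group as separate animals. Genotype, treatment and replicate number were taken from the sample titles and the clock time from the time label. The separate treatment tag followed the clock time and differed from the title in 24 libraries, so the titles, which fit the series' design text, were used. No library was left out, and no label named a sequencing batch.

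Per the labels' protocols, RNA was purified on Direct-zol columns, libraries were made with the TruSeq RNA v2 kit, which selects poly(A) RNA and does not mark strand, and single reads of 50 cycles were sequenced on a HiSeq. Novoalign (version not given) and the build GRCm38 appear in the submitters' processing notes. The annotation and the rule for reads that match several genes were not given in the sources used here. The deposited values were FPKM (fragments scaled by gene length and by library size) for 15041 Ensembl genes, as the authors computed them and named in the header of the deposited table. Reads shared between near-identical genes (the Cyp2a, Cyp2b, Cyp2c, Cyp4a, Mup, Saa, Sult2a, Gst and haemoglobin families, and processed pseudogenes) may have been split or moved by that counting. Values of genes lying antisense to another gene are uncertain because the kit does not mark strand.

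The steps between low FPKM values showed the reads behind them: whole reads were recovered for 15040 genes (99.99%, within a relative tolerance of 1e-11). Summed over genes, these gave a depth of 9726026 to 20016584 reads per library, and 1 read in a gene of 1000 bases was worth 0.051 to 0.104 FPKM. Mitochondrial genes took 2.82% to 6.91% of reads and Alb took 7.15% to 14.66%. No library pair within a group was a duplicate (chi-square per degree of freedom 9.8 to 274.2). Positions came from GENCODE release M21 on GRCm38, in which 14518 IDs matched. Gene lengths implied by the FPKM were within 5% of those of M21 for 60.2% of genes. The annotation behind the values, its rule for gene length, or both therefore differed from those used here. Symbols are those of the deposited table, where 83 occur more than once, and tables were joined by Ensembl ID.

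The test had been planned for read counts. Because the values were FPKM, limma (3.58.1, in R 4.3.3) was run on log2(FPKM × scale factor + 0.5), with the pseudocount of 0.5 FPKM. Fold changes are therefore on this scale, which understates the change of low genes. Scale factors were trimmed means of M-values (trim 30% of fold changes, 5% of levels) computed from the recovered reads, and ranged from 0.81 to 1.3. Genes with at least 0.5 FPKM in at least 3 libraries were tested (13765 tested, 1276 removed). A single fit with 16 group means over the 48 libraries, with a mean-variance trend (limma-trend), gave each contrast, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The contrasts were the ethanol effect in each genotype as the mean of 4 times and at each time, the difference of these effects between genotypes, the effect of the knockout label in each treatment, time of day in each of the 4 arms (3 contrasts tested jointly), and the time dependence of the ethanol effect and of the knockout effect. The fit shares its estimate of spread among all groups.

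Gene lists were fixed before the data were examined: 34 lists of metabolic and stress pathways, sex-dependent and nuclear receptor programmes, clock genes and cell type markers, with 523 distinct genes of which 504 were found. Each list was compared with the other tested genes by camera (limma) with the correlation between genes preset to 0.01, and p-values were adjusted over the 34 lists within a contrast. Camera with an estimated correlation and fry were alternatives. Counts of called members are given over all genes tested and adjusted over the list alone.

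Named genes followed a rule fixed before the data were examined. For each contrast that is a mean of 4 times it took the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 1 and the same sign at each of the 4 times. For time of day it took the 10 widest ranges, and for time dependence the 5 smallest adjusted p. It also took up to 4 members with the smallest adjusted p of each list described, and, whatever their result, Nr0b2, Nr1d1, Nr1d2, Arntl, Clock, Per1, Per2, Per3, Cry1, Dbp, 6 Cyp4a genes, Ppara, Cyp2e1, Cyp7a1 and Cyp8b1. Some genes that met this rule are not reported here. Peak hours of clock genes were estimated by a cosine with a period of 24 h fitted to the 4 times.

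The procedure was tested on simulated data with 13765 genes, in which 50 genes were changed at each of 1.5-, 2-, 4- and 8-fold. For the ethanol effect in wild type it called 70%, 90%, 96% and 100% of them with 9 false calls. For the difference between genotypes the shares were 54%, 90%, 96% and 100% with 14 false calls, for wild type at 6am alone 32%, 80%, 90% and 98% with 16 false calls, and for time of day in wild-type controls 34%, 76%, 94% and 96% with 10 false calls. Simulated genes were independent, with a spread per gene shared by all groups and no livers that stood apart. These shares and false calls may therefore not hold in the more variable groups.

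Alternatives fixed before the data were examined were library totals alone, median-of-ratios size factors, other filters on low values, only the libraries compared in the fit, the replicate number as a block, leaving out each library, and the other list tests. Chosen after seeing the data were pseudocounts of 0.1 and 1, voom on the recovered reads, array weights, leaving out the 4 libraries that were the lowest of their group in mean rank correlation with it and were under 0.965, and leaving out 6pm. Of the 8 libraries under 0.965, the 4 others were kept there, since 6 of the 8 are all the ethanol libraries labelled knockout of 6pm and midnight; leaving out all 8 was tried for the acute phase genes alone, over 6am and noon, as were single times and leaving out each library. Tables and figures were made with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9), and copies of genes were found with minimap2 2.31-r1302.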

Results

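Liver RNA was sequenced from wild-type mice and from mice labelled as knockouts of SHP, an orphan nuclear receptor encoded by Nr0b2 that represses other transcription factors. The mice had taken a control or an ethanol liquid diet over 10 days and then a single dose of maltose dextrin or of ethanol. The series' title places the work on the relation of SHP, the clock repressor REV-ERBα (Nr1d1) and the CYP4A fatty acid hydroxylases to alcoholic liver injury. Each of the 16 groups (genotype, treatment and clock time) held 3 livers, so that each genotype and treatment had 12 libraries over 4 times. Libraries held 9726026 to 20016584 reads in genes, and 13765 genes were tested. Adjusted p-values are from limma with Benjamini-Hochberg adjustment unless camera, the test of a gene list against the other tested genes, is named. Errors in parentheses after log2 fold changes are standard errors.

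Nr0b2 (ENSMUSG00000037583, chromosome 4, 133553376 to 133556536, GRCm38) was read in all 48 libraries, with 62 to 875 reads in each. Its level was 22.1 ± 9.6 FPKM in wild-type controls (SD, n = 12, range 5.67 to 41.5) and 21.9 ± 9.53 FPKM in controls labelled knockout (n = 12, 4.22 to 37.2). In ethanol mice it was 12.4 ± 9.07 FPKM in wild type (n = 12, 3.71 to 27.9) and 11.7 ± 6.14 FPKM in libraries labelled knockout (n = 12, 3.48 to 21.6). At 6am the 3 wild-type control livers had 25, 41.5 and 21.9 FPKM and the 3 labelled knockout 19.6, 18.6 and 33.9 FPKM. The difference of knockout-labelled from wild-type libraries was -0.18 (0.26, adjusted p = 0.626) in controls and 0.10 (0.26, adjusted p = 0.795) in ethanol mice. The genotype is therefore taken from the label alone in what follows, and directions between genotypes are those of the labels. Which part of the gene was targeted is not given in the sources used here, so reads from a part that the targeting left in place are not separated in these gene-level values. Ethanol lowered Nr0b2 in wild type by -0.95 (0.26, adjusted p = 0.00486) and in libraries labelled knockout by -0.67 (0.26, adjusted p = 0.0438). The second call was lost by voom (adjusted p = 0.0513) and in 15 of 24 fits that left out 1 library.

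The 6 measured Cyp4a genes, whose products hydroxylate fatty acids, moved in opposite directions with ethanol: 4 rose and 2 fell in wild type, and likewise 4 and 2 in the knockout-labelled arm (4 and 2 adjusted over the list alone in both). They lie on chromosome 4 (Cyp4a10 at 115518264 to 115533649), within 20 Mb of Nr0b2, and share reads, so their separate levels are uncertain. Cyp4a10 went from 49.0 ± 25.6 to 292 ± 363 FPKM with ethanol in wild type and from 19.6 ± 11.4 to 87.1 ± 83.2 FPKM in the knockout-labelled arm (SD, n = 12 each), log2 changes of 2.36 (0.40, adjusted p = 2.87e-05) and 2.05 (0.40, adjusted p = 0.000194). Cyp4a14 went from 57.1 ± 41.1 to 642 ± 890 and from 27.4 ± 14.4 to 198 ± 276 FPKM, with changes of 3.41 (0.51, adjusted p = 3.98e-06) and 2.30 (0.51, adjusted p = 0.000789). Cyp4a31 rose by 1.73 and 1.15, and Cyp4a32 by 0.72 and 0.93, in the wild-type and knockout-labelled arms. The male-predominant Cyp4a12a fell by 2.2 (adjusted p = 2.24e-06) and by 1.21 (adjusted p = 0.00389), and Cyp4a12b fell by 2.29 and by 1.85. None of the 6 had an ethanol effect called different between genotypes, with -1.11 (0.73, adjusted p = 0.384) for Cyp4a14 and 0.99 (0.45, adjusted p = 0.177) for Cyp4a12a. As a list the family was not called in any comparison (camera adjusted p = 0.48 for wild type, 0.45 for the knockout-labelled arm and 0.914 for the difference, where median and mean were below 0 and the test's direction was up). The wild-type ethanol liver of 6am replicate 1 had 1418 FPKM of Cyp4a10 and 3407 of Cyp4a14. Ppara fell by 0.36 in wild type (adjusted p = 0.0437), a call lost with library totals alone (adjusted p = 0.0526), with the replicate block (0.0512) and in 16 of 24 fits that left out 1 library.

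**Figure D1:**
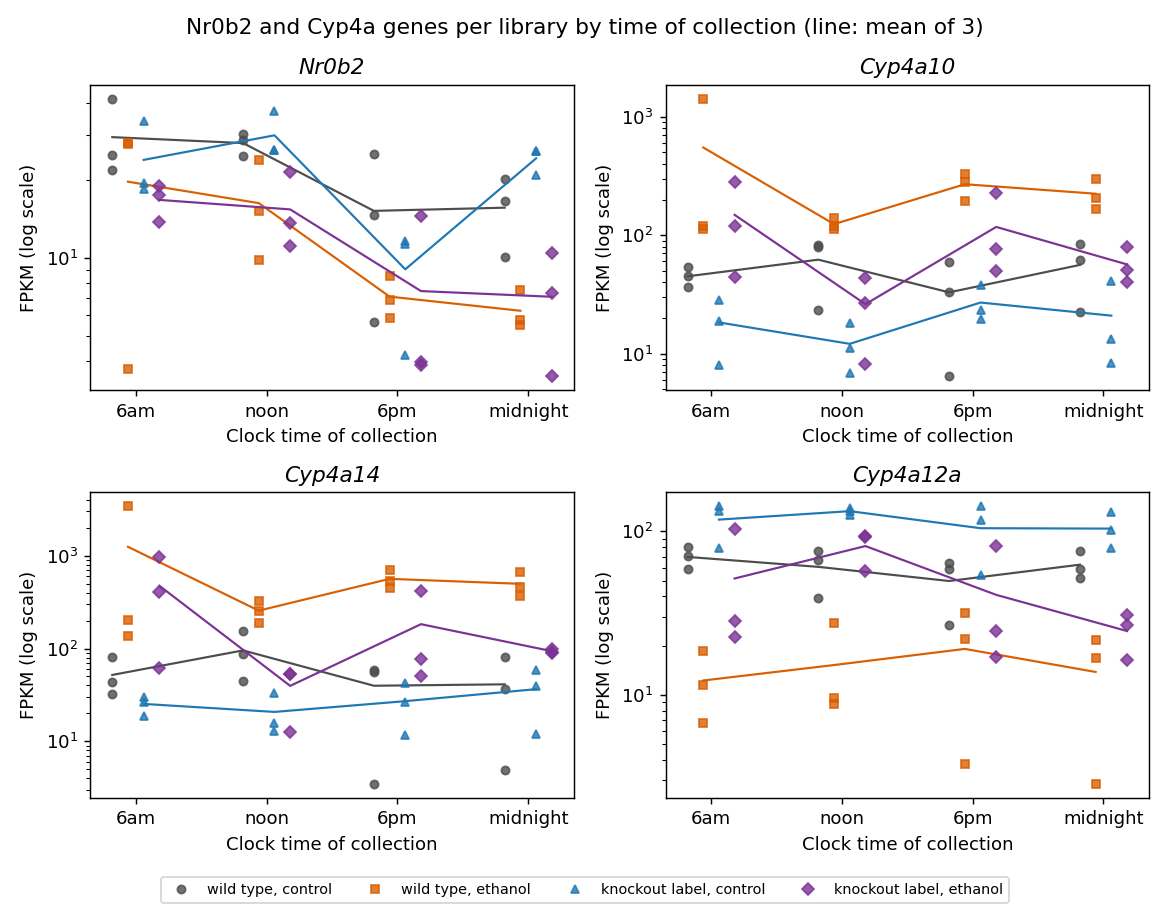
FPKM (log axis) of Nr0b2, Cyp4a10, Cyp4a14 and Cyp4a12a in each library by clock time, coloured by genotype label and treatment, with lines through the means of 3 libraries. Nr0b2 of the libraries labelled knockout (3.48 to 37.2 FPKM) covers much of the range of wild type (3.71 to 41.5 FPKM).

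Ethanol in wild type raised drug metabolism genes and lowered male-predominant and lipogenic genes (list tests with adjusted p = 0.0379, 0.101 and 0.101 in turn with an estimated correlation). Cyp2b10, a drug-metabolising cytochrome and textbook target of the receptor CAR, rose from 1.41 ± 1.16 to 267 ± 259 FPKM (SD, n = 12), a log2 change of 6.56 (0.39, adjusted p = 1.44e-14). Its relatives Cyp2a22 (5.26), Cyp2b9 (4.74) and Cyp2a5 (3.89) rose too, as did the glutathione transferase Gstm3 (3.41), the acute phase gene Orm3 (2.99), Derl3, which acts in ER-associated degradation, (2.97), the efflux pump Abcc4 (2.95) and the metallothionein Mt2 (2.93, adjusted p = 0.000654). The male-predominant steroid enzyme Hsd3b5 fell by 5.62 (0.57, adjusted p = 2.14e-09), and the pseudogene Serpina4-ps1 changed by -4.54. The major urinary protein genes Mup21 (-4.68), Mup7 (-3.56), Mup14 (-3.37), Mup20 (-3.27) and Mup11 (-3.12) fell. So did Fabp5 (-3.07), whose product binds fatty acids, Cib3 (-3.02) and the desaturase Scd1 (-2.99, SE 0.26, adjusted p = 9.89e-11). The Cyp2a, Cyp2b, Gst and Mup genes share reads within their families.

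By list, 15 of 16 male-predominant genes fell in wild type with ethanol (16 adjusted over the list alone, median -2.17, camera adjusted p = 2.76e-13, adjusted p = 0.101 with an estimated correlation). These included Ugt2b38 (-2.15) and Elovl3 (-2.82). Female-predominant genes rose (11 of 13, 12 over the list alone, camera adjusted p = 9.99e-06, adjusted p = 0.112 with an estimated correlation). These included Acot3 (2.62) and Cyp2a4 (2.66). Of 20 lipogenic genes 17 fell (17 adjusted over the list alone, camera adjusted p = 1.05e-12, adjusted p = 0.101 with an estimated correlation). Among them Pnpla3 was at -2.86, Elovl5 at -1.26 and Fads1 at -0.91. CAR and PXR targets rose (16 of 18, 17 over the list alone, median 0.74, camera adjusted p = 7.12e-12). Among them Cyp2c29 was at 2.42 and the reductase Por at 1.48. The CAR and PXR call was the only one of 47 list calls in 170 tests that held with an estimated correlation (adjusted p = 0.0379).

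Of 20 NRF2 and glutathione genes 14 rose and 2 fell in wild type (the same numbers over the list alone, camera adjusted p = 8.27e-10, adjusted p = 0.101 with an estimated correlation), led by Nqo1 (2.10), Gstm1 (2.17) and Gsta2 (2.91). ER stress and amino acid response genes rose (13 of 20, against 13 higher and 1 lower over the list alone, camera adjusted p = 1.09e-05, adjusted p = 0.314 with an estimated correlation). Among them Atf5 was at 1.10, Psat1 at 1.90, Trib3 at 2.42 and Asns at 1.47. Heat shock genes rose in 9 and fell in 1 of 11 (the same over the list alone, camera adjusted p = 2.93e-05, adjusted p = 0.112 with an estimated correlation). Among them Hspb1 was at 1.13 and Hsp90aa1 at 0.74. Interferon-response genes fell (14 of 20, 17 over the list alone, camera adjusted p = 4.04e-09, adjusted p = 0.112 with an estimated correlation). Among them Ifit3 was at -1, Irf7 at -1.19 and Ifit1 at -0.91. Smaller falls were called for cholesterol synthesis and uptake (9 lower and 1 higher of 24, the same over the list alone, camera adjusted p = 0.00359) and gluconeogenesis and glucose handling (9 lower of 20, 10 over the list alone, 0.0041), with adjusted p = 0.833 and 0.649 with an estimated correlation. Markers of Kupffer cells, the liver's macrophages (6 lower and 1 higher of 13, 8 and 1 over the list alone, camera adjusted p = 0.0052), and of lymphocytes (4 lower of 13, 4 over the list alone, 0.00809) fell too, with adjusted p = 0.802 and 0.672 with an estimated correlation.

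In all, limma called 4171 genes for ethanol in wild type, 2287 higher and 1884 lower, and 5514 had an unadjusted p under 0.05. More than 2-fold changes made up 293 of the calls.

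Ethanol in the knockout-labelled arm also raised drug metabolism genes and lowered lipogenic ones, and together with them raised acute phase genes and lowered cell cycle genes. With an estimated correlation these list calls were lost (adjusted p = 0.556 for acute phase genes and 0.261 for the other 3). Cyp2b9 rose by 5.18 (0.55, adjusted p = 1.9e-08), Cyp2b10 by 3.94 (0.39, adjusted p = 5.22e-09), Cyp2a5 by 2.98 and Cyp2a4 by 2.78. The metallothioneins Mt2 and Mt1 rose by 4.06 and 3.71, Orm3 by 3.34, the iron-binding lipocalin Lcn2 by 3.26 (0.79, adjusted p = 0.00185) and the sulfotransferase Sult1e1 by 2.99. The elongase Elovl3 (-3.31), Chrna4 (-3.13), Mup20 (-3.06), Mup21 (-2.97), the immunoglobulin gene Ighm (-2.93) and Hsd3b5 (-2.74, SE 0.57, adjusted p = 0.000337) fell. H2-Q2 (-2.64), the transporter Slco1a1 (-2.59), Pnpla3 (-2.58) and Scd1 (-2.44) fell too.

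Cell cycle genes fell in 21 of 22 (21 adjusted over the list alone, median -1.19, camera adjusted p = 2.68e-16, adjusted p = 0.261 with an estimated correlation). These included Mki67 (-1.5), Aurka (-1.29), Ccnb2 (-1.78) and Birc5 (-1.2). Acute phase genes, whose secreted products rise in inflammation, were higher in 16 and lower in 1 of 22 (the same over the list alone, median 1.25, camera adjusted p = 8.76e-07, adjusted p = 0.556 with an estimated correlation). Among them Lbp was at 1.45, Itih4 at 1.5 and Apcs at 2.11. The mean log2 level of the list was highest, 10.47 and 10.36, in the knockout-labelled ethanol livers of noon replicate 1 and 6pm replicate 1, against 6.94 to 7.44 in the others of these 2 groups. At 6am and midnight it was 7.68 to 8.84 in the 6 knockout-labelled ethanol livers and 6.68 to 7.49 in those of wild type. Over the 4 times the same list had 2 higher and 4 lower in wild type (2 and 5 over the list alone, camera adjusted p = 0.828). By time, its wild-type medians were 0.71 at 6am (camera adjusted p = 0.0427, adjusted p = 0.876 with an estimated correlation), 0.5 at noon (0.095), -1.05 at 6pm (camera adjusted p = 0.00148, adjusted p = 0.658 with an estimated correlation) and -0.07 at midnight (0.374). Interferon-response genes fell (16 of 20, 16 over the list alone, camera adjusted p = 5.67e-12), lipogenic genes fell in 14 and rose in 1 of 20 (14 and 2 over the list alone, 1.84e-08), and CAR and PXR targets rose in 11 and fell in 2 of 18 (11 and 2 over the list alone, 3.55e-05). Each of these 3 had adjusted p = 0.261 with an estimated correlation. ER stress genes rose (16 of 20, 17 over the list alone, camera adjusted p = 5.73e-06, adjusted p = 0.359 with an estimated correlation). Female-predominant genes rose in 10 and fell in 1 of 13 (10 and 1 over the list alone, camera adjusted p = 4.97e-05, adjusted p = 0.261 with an estimated correlation), and male-predominant genes fell in 7 and rose in 1 of 16 (8 and 1 over the list alone, 0.0052, adjusted p = 0.863 with an estimated correlation). Pericentral genes, expressed by hepatocytes around the central vein, rose in 6 and fell in 2 of 13 (7 and 2 over the list alone, camera adjusted p = 0.00531, adjusted p = 0.369 with an estimated correlation). Among them Cyp2c37 was at 2.40 and Rhbg at 1.18.

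Calls in the knockout-labelled arm numbered 4348, 2307 higher and 2041 lower, with 5697 at an unadjusted p under 0.05 and 257 over 2-fold. Library totals alone moved the median gene by -0.203 and gave 542 higher and 6759 lower (7.4% higher against 53.1%). Of the ethanol calls, 1118 were higher and 806 lower in both genotypes (383 and 279 for independent lists) and 84 went opposite ways, with r = 0.62 (rho 0.55) across genes, which are not independent replicates.

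The test of the difference asked which ethanol effects differed by genotype label. Among drug metabolism genes the difference, knockout-labelled minus wild type, was -3.29 for Cyp2a22 (0.33, adjusted p = 1.15e-07), -3.12 for Gstm3 (0.38, adjusted p = 3.44e-06), -2.62 for Cyp2b10 (0.55, adjusted p = 0.00313), -2.38 for Cyp2c55 and -2.08 for Gsta2, while Cyp2b9 was at 0.43 (0.77, adjusted p = 0.794). It was -2.43 for the carbonyl reductase Cbr3, -1.95 for the transporter Slco1a4, -1.84 for Acot2, and -2.17 for the apolipoprotein Apoa4, with -2.19 for Gm10680, which lies antisense to Apoa4 (chromosome 9, 46242621 to 46243529) and whose reads cannot be told from it. It was above 0 for the serum amyloid genes Saa2 (4.82, SE 1.46, adjusted p = 0.0354), Saa1 (4.37, SE 1.38, adjusted p = 0.0437) and Saa3 (2.31, adjusted p = 0.0275). It was also above 0 for genes that fell in wild type with ethanol, Mup7 (3.14), Mup11 (3.08), Mup17 (3.07), Serpina4-ps1 (2.93), Hsd3b5 (2.88), Mup14 (2.86) and Mup1 (2.32, adjusted p = 0.00314). In controls labelled knockout, Mup14 (-5.57), Mup17 (-5.32), Mup11 (-5.02), Serpina4-ps1 (-3.72) and Mup7 (-3.62) were already lower than in wild type, and Gstm3 (2.49) higher. For these genes a different response to ethanol is not separated from a different starting level. Cyp2e1, the ethanol-oxidising cytochrome, differed by 0.82 (0.18, adjusted p = 0.00472), with a change of -0.13 (adjusted p = 0.5) in wild type and 0.70 (adjusted p = 0.000102) in the knockout-labelled arm.

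Of 22 cell cycle genes 16 had a lower difference (21 adjusted over the list alone, median -0.94, camera adjusted p = 3.4e-14, adjusted p = 0.344 with an estimated correlation). These included Mcm2 (-1.55) and Ccna2 (-1.03). NRF2 and glutathione genes were lower in 11 of 20 (13 lower and 1 higher over the list alone, camera adjusted p = 5.57e-10, adjusted p = 0.259 with an estimated correlation). Among them Srxn1 was at -1.60 and Gsta1 at -3.31. Acute phase genes were higher in 9 of 22 (17 over the list alone, median 1.2, camera adjusted p = 7.14e-09, adjusted p = 0.54 with an estimated correlation). Among them Itih4 was at 1.38, Saa4 at 1.19 and Fgg at 1.22. Male-predominant genes were higher in 8 of 16 (10 over the list alone, camera adjusted p = 1.35e-06, adjusted p = 0.54 with an estimated correlation). Among them Ugt2b38 was at 1.57 and Serpina1e at 2.06. Heat shock genes were lower in 7 and higher in 1 of 11 (8 and 1 over the list alone, camera adjusted p = 0.000211, adjusted p = 0.344 with an estimated correlation). Among them Hsp90aa1 was at -0.91 and the cold-inducible Cirbp at 0.79. CAR and PXR targets were lower in 3 of 18 (5 over the list alone, camera adjusted p = 0.0282, adjusted p = 0.835 with an estimated correlation), with Cyp3a11 at -1.53, and gluconeogenesis and glucose handling genes were higher in 3 of 20 (3 over the list alone, 0.0352, adjusted p = 0.91 with an estimated correlation). Fbp1 was at 0.66. In controls labelled knockout the cell cycle list and the NRF2 and glutathione list were already called higher than in wild type, and the male-predominant list lower (camera with the preset correlation). For these lists too, a different response to ethanol is not separated from a different starting level.

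The difference called 1102 genes, 508 higher and 594 lower, with 3167 at an unadjusted p under 0.05 and 150 over 2-fold. The ethanol effect was the larger in size in wild type for 567 of them and in the knockout-labelled arm for 535. Library totals alone moved the median gene by -0.199 and gave 193 higher and 3635 lower (5% higher against 46.1%), array weights called 2842, the fit without the 4 libraries that stood apart (each the lowest of its group in rank correlation with it, and under a limit) 1717 and the fit without 6pm 602. Calls were lost for Saa2 (without 6pm adjusted p = 0.169, voom 0.0536, 8 of 48 fits that left out 1 library), Saa1 (without 6pm 0.172, without the 4 libraries 0.0587, 31 of 48 fits), Saa3 (without 6pm 0.159, voom 0.144), Hsd3b5 (without 6pm 0.0785, pseudocount 0.1 0.0621, voom 0.182), Acot2 (without 6pm 0.12), Mup14 (voom 0.136), Mup1 (voom 0.0779) and Cyp2b10 (voom 0.136).

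**Figure D2:**
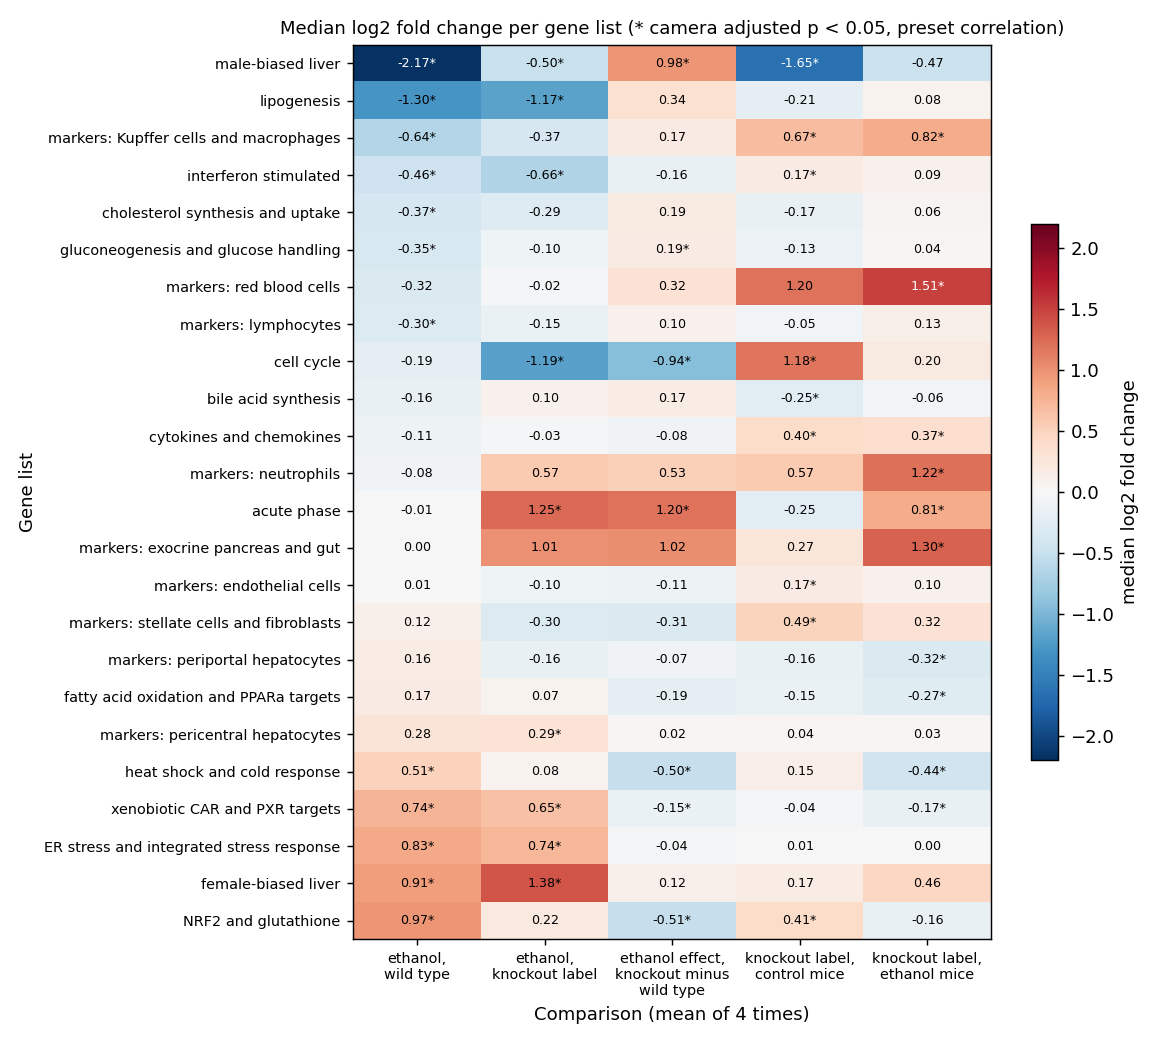
Heat map of the median log2 fold change of each of the 24 gene lists called in at least 1 of the 5 comparisons, with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. Cell cycle genes have a median of 1.18 in controls labelled knockout against wild type and of -1.19 for ethanol in the knockout-labelled arm.

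In controls, libraries labelled knockout had higher cell cycle genes and lower male-predominant genes than wild type (both lists with adjusted p = 0.516 with an estimated correlation). Asparagine synthetase Asns was higher by 3.51 (0.20, adjusted p = 7.59e-16; 23.4 ± 6.54 against 1.55 ± 1.1 FPKM, SD, n = 12), the sulfotransferase Sult2a7 by 4.12, the imprinted RNA H19 by 2.56, Fam131c by 2.73 and Gstm3 by 2.49. BC002163 (4.16), Gm5506 (3.87), Gm10036 (3.62), Gm17639 (3.17) and Gm10680 (2.32) were higher as well. The urinary protein genes Mup14 (-5.57), Mup17 (-5.32), Mup11 (-5.02), Mup16 (-3.90), Mup7 (-3.62) and Mup12 (-3.39) were lower, as were Serpina4-ps1 (-3.72), the complex I subunit Ndufs5 (-3.54, SE 0.12, adjusted p = 4.18e-23; 0.539 ± 0.246 against 10.8 ± 1.01 FPKM, SD, n = 12), Cib3 (-3.52) and the adipokine Serpina12 (-3.23). Cyp2e1 was lower by -0.83 (0.13, adjusted p = 1.04e-05) and Cyp4a10 by -1.39 (0.40, adjusted p = 0.00827), the only one of the 6 Cyp4a genes called (1 over the list alone). Cyp4a12a (0.77, SE 0.32, adjusted p = 0.0611) was called with library totals alone (adjusted p = 0.023), with only the libraries compared (0.00283), with array weights (0.0174) and without the 4 libraries that stood apart (0.0343).

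In 25 genes every one of the 24 libraries labelled knockout lay beyond every one of the 24 wild-type libraries, 14 higher and 11 lower, against 0 in 99 permutations of the genotype labels. Of the 24 with a position, 13 (54.2%) lay within 20 Mb of Nr0b2, against 412 of 13258 other tested genes (3.1%). Among the 13 were Ndufs5, Eno1 (-1.49), Gm13152 (-2.05), Gm13157 (-0.78), Fbxo44 (-1.56), Miip (-1.24), Ccdc21 (-0.98), Hdac1 (-0.83), Gm12901 (3.20), Fam131c (2.73), Tmem51 (1.63) and Gm10565 (0.92). These genes were chosen after their values were seen.

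**Figure D3:**
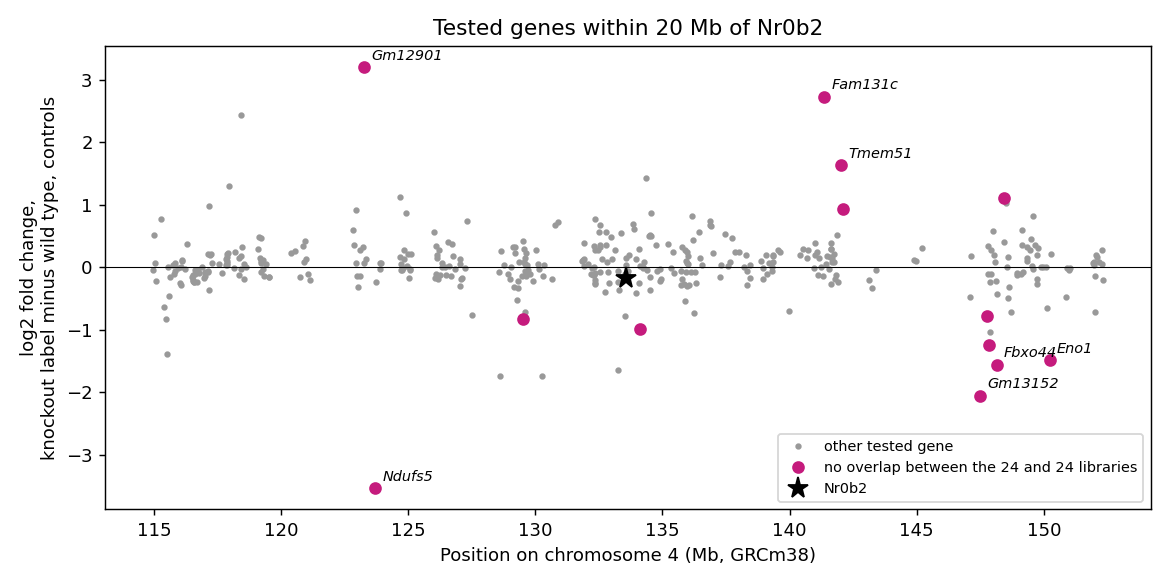
Log2 fold change of knockout-labelled against wild-type controls for the tested genes of chromosome 4 within 20 Mb of Nr0b2, by position in Mb (GRCm38), with the genes that separate all libraries by genotype label in magenta. The 13 separating genes range from -3.54 (Ndufs5) to 3.20 (Gm12901).

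Cell cycle genes were higher in 21 of 22 in controls labelled knockout (21 adjusted over the list alone, median 1.18, camera adjusted p = 8.93e-16, adjusted p = 0.516 with an estimated correlation). Among them Mki67 was at 1.46, Aurka at 1.22 and Ccnb2 at 1.66. Male-predominant genes were lower in 14 of 16 (14 lower and 1 higher over the list alone, camera adjusted p = 1.43e-08, adjusted p = 0.516 with an estimated correlation). NRF2 and glutathione genes were higher in 11 and lower in 1 of 20 (the same over the list alone, camera adjusted p = 9.07e-05, adjusted p = 0.546 with an estimated correlation). Among them Gsta4 was at 1.33 and Srxn1 at 1.22. Markers of non-parenchymal cells were higher: stellate cells and fibroblasts in 9 of 14 (12 over the list alone, camera adjusted p = 0.000109, adjusted p = 0.516 with an estimated correlation), with Timp1 at 1.23 and Col1a1 at 1.06, Kupffer cells in 11 of 13 (11 over the list alone, 0.00185), with Cd68 at 1, and endothelial cells in 4 of 13 (4 over the list alone, 0.0196), with Stab1 at 0.40. The Kupffer and endothelial lists each had adjusted p = 0.905 with an estimated correlation. Cytokines and chemokines were higher in 6 of 17 (7 over the list alone, camera adjusted p = 0.00854), with Il1rn at 1.38, and interferon-response genes in 7 of 20 (7 over the list alone, 0.0214), with Oas1a at 0.68. Both had adjusted p = 0.905 with an estimated correlation. Bile acid synthesis genes were lower in 4 of 13 (4 over the list alone, camera adjusted p = 0.0303, adjusted p = 0.824 with an estimated correlation), namely Baat (-0.40), Scp2 (-0.53), Cyp7b1 (-1.11) and Cyp27a1 (-0.30), while Cyp7a1, the rate-limiting enzyme, was at -0.25 (0.25, adjusted p = 0.46) and Cyp8b1 at -0.25 (0.22, adjusted p = 0.388). In all 4457 genes were called, 2124 higher and 2333 lower, with 5908 at an unadjusted p under 0.05 and 264 over 2-fold. Library totals alone moved the median gene by 0.111 and gave 4135 higher and 812 lower (83.6% higher against 47.7%).

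In ethanol mice, libraries labelled knockout had higher acute phase genes and Kupffer cell markers than wild type, and lower Cyp2a22 (-3.48), Cyp2b10 (-3.03) and Slco1a4 (-2.06). Both list calls were lost with an estimated correlation (adjusted p = 0.799). Saa2 was higher by 4.65 (1.03, adjusted p = 0.00109) and Saa1 by 4.06 (0.98, adjusted p = 0.00235; 4074 ± 7181 against 75.1 ± 120 FPKM, SD, n = 12). Sult2a7 (5.01), BC002163 (4.23), Gm17639 (3.88), Gm5506 (3.85), Gm10036 (3.69) and Asns (2.92) were higher again, and so were the imprinted RNA Meg3 (3.13) and the melanin enzyme Dct (2.81). Ndufs5 (-3.51), Mup14 (-2.71), Mup17 (-2.25), Mup-ps16 (-2.23), Gm13775 (-2.23), Serpina12 (-2.12) and Cib3 (-2.06) were lower. Cyp4a12a was higher by 1.77 (0.32, adjusted p = 0.000112), while Cyp4a10 (-1.70, adjusted p = 0.00207) and Cyp4a14 (-1.94, adjusted p = 0.00503) were lower (1 higher and 2 lower over the list alone). Cyp7a1 was lower by -0.90 (0.25, adjusted p = 0.0067).

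Acute phase genes were higher in 16 of 22 (17 higher and 1 lower over the list alone) and Kupffer cell markers in 12 of 13 (13 over the list alone), each with camera adjusted p = 1.99e-05 and with adjusted p = 0.799 with an estimated correlation. Higher too were red cell genes in 5 of 7 (5 over the list alone, median 1.51, camera adjusted p = 0.00491), with Hba-a2 at 1.65, cytokines and chemokines in 3 of 17 (3 over the list alone, 0.00672), with Cd14 at 1.22, neutrophil markers in 4 of 7 (5 over the list alone, 0.00724), with S100a8 at 2.05, and markers of the exocrine pancreas and gut in 5 of 9 (8 over the list alone, 0.01), with Ctrb1 at 2.56. These 4 lists each had adjusted p = 0.799 with an estimated correlation. Fatty acid oxidation genes and PPARα targets were lower in 8 of 26 (9 over the list alone, camera adjusted p = 0.00724, adjusted p = 0.799 with an estimated correlation). Among them Acot2 was at -1.53 and Acot1 at -1.69. Heat shock genes were lower in 5 and higher in 2 of 11 (6 and 2 over the list alone, 0.0215), CAR and PXR targets lower in 6 and higher in 1 of 18 (7 and 2 over the list alone, 0.044), with Cyp2c55 at -2.02, and periportal genes lower in 5 and higher in 1 of 14 (5 and 1 over the list alone, 0.0483), with Cyp2f2 at -1.64. These 3 lists each had adjusted p = 0.799 with an estimated correlation. The mean log2 level of the exocrine markers was 8.21 in the knockout-labelled ethanol liver of midnight replicate 0 and at most 2.27 in every other library, and that of the neutrophil markers was highest, 3.95, in the knockout-labelled ethanol liver of 6pm replicate 1. In all 3899 genes were called, 1730 higher and 2169 lower, with 5593 at an unadjusted p under 0.05 and 177 over 2-fold. Library totals alone gave 914 higher and 3615 lower (20.2% higher against 44.4%).

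**Figure D4:**
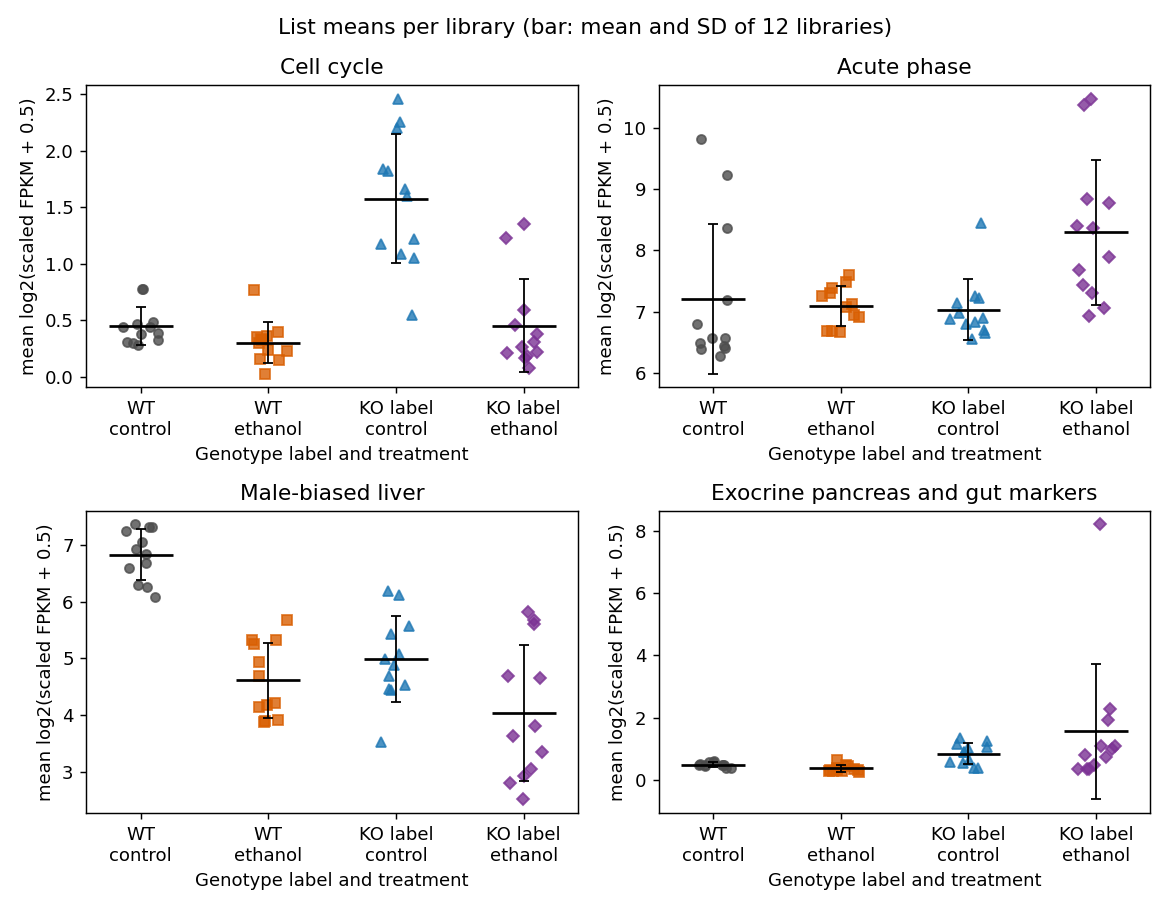
Mean log2(scaled FPKM + 0.5) of the cell cycle, acute phase, male-predominant and exocrine pancreas lists in each library, by genotype label and treatment, with bars at the mean and SD of 12 libraries. The cell cycle score lies between 0.55 and 2.46 in controls labelled knockout and between 0.28 and 0.78 in wild-type controls.

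Clock genes changed with the time of collection in each arm. All mice received the binge at 9am, so clock time and time since the binge cannot be told apart between times. In wild-type controls the activator Arntl (BMAL1) stood at 14.8 ± 0.43 FPKM at 6am, 5.79 at noon, 0.65 ± 0.26 at 6pm and 8.45 at midnight (SD, n = 3), and Nr1d1, which represses it, at 4.23, 38.9, 10.4 and 1.27 FPKM. The output factor Dbp rose from 1.01 ± 0.26 at 6am to 30.2 ± 14.5 FPKM at 6pm. The genes with the widest ranges there were Mt2, Mt1, Lcn2, Elovl3, Dbp, Nr1d1, Arntl, Gm129, Ppp1r3c and Usp2, with adjusted p from 9.71e-13 (Arntl) to 0.0432 (Lcn2). The call of Lcn2 was lost in 9 of 12 fits that left out 1 library. The mean log2 level of acute phase genes was 9.81 and 9.23 in the wild-type control livers of 6pm replicates 0 and 2, against 6.81 in replicate 1, 6.57 to 8.36 at midnight and 6.28 to 6.58 at 6am and noon. In wild-type ethanol livers they were the cell cycle inhibitor Cdkn1a (48.2 ± 20.1 FPKM at 6pm against 0.69 ± 0.31 at noon), the hormone Fgf21, Mt2, Chrna4, Dbp, Upp2, Egr1, Cidec, Mt1 and Igfbp1, with adjusted p from 9.57e-08 (Dbp) to 0.0338 (Mt2). Fits that left out 1 library lost the calls of Mt1 and Mt2 in 5 of 12 each and of Igfbp1 in 4 of 12. In controls labelled knockout they were Nr1d1, Elovl3, Dbp, Gm14097, Clic3, Upp2, Arntl, Gm129, Usp2 and Loxl4, with adjusted p from 9.8e-12 (Arntl) to 0.0126 (Clic3). In ethanol livers labelled knockout they were the iron hormone gene Hamp, Mup7, Dbp, Upp2, Mup11, Cyp2b10, Fgf21, Selenbp2, Nr1d1 and Cela2a, with adjusted p from 4.8e-10 (Dbp) to 0.0207 (Cela2a). Cela2a is a gene of the exocrine pancreas, and 7 of 9 exocrine markers were called for time in that arm (7 over the list alone), where the midnight replicate 0 had their mean log2 level of 8.21 and every other library at most 2.27. Of the 7 clock activators and 12 output and repressor genes, 6 and 10 changed with time in wild-type controls (6 and 12 over the list alone), 5 and 8 in wild-type ethanol livers (7 and 9), 6 and 10 in controls labelled knockout (6 and 11) and 7 and 11 in ethanol livers labelled knockout (7 and 11).

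Calls for time of day numbered 1150 in wild-type controls, 2791 in wild-type ethanol livers, 1755 in controls labelled knockout and 5253 in ethanol livers labelled knockout. The last count fell to 229 when only the libraries compared were fitted, which also ended the calls of Hamp (adjusted p = 0.0864), Mup7 (0.104), Upp2 (0.0519), Mup11 (0.103), Cyp2b10 (0.0624), Fgf21 (0.124), Selenbp2 (0.116) and Cela2a (0.44), and in controls labelled knockout the count fell to 1107. Leaving out a single library moved the count to 715 or 760 in wild-type controls (6pm replicate 2 or 0), to 1669 or 1856 in wild-type ethanol livers (6pm replicate 0 or noon replicate 2) and to 819 in controls labelled knockout (6pm replicate 2). Array weights gave 3213, 6331 and 4407 for the first 3 arms, and Lcn2 (0.102) and Mt2 (0.259) were not called in wild-type controls by the fit of the libraries compared and by voom, respectively.

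With ethanol, clock genes of wild-type livers rose and fell at earlier hours. Arntl was lower with ethanol at 6am (-1.21, SE 0.23, adjusted p = 0.000594) and noon (-1.90, adjusted p = 2.07e-06) and higher at 6pm (2.72, SE 0.23, adjusted p = 1.13e-09), where it reached 7.33 ± 1.39 FPKM (SD, n = 3). Nr1d1 was higher with ethanol at 6am in wild type (2.48, SE 0.46, adjusted p = 0.000453) and in the knockout-labelled arm (2.19, SE 0.46, adjusted p = 0.00272), and Nr1d2 by 1.61 and 1.60. Dbp was higher at 6am (2.24) and lower at 6pm (-2.43) in wild type, Cry1 lower at 6am (-2.07) and higher at 6pm (1.42), Per2 higher at noon (1.19) and lower at midnight (-1.5), Per3 higher at noon (1.96) and Clock higher at 6pm (1.19). In the knockout-labelled arm Arntl was lower at noon (-1.70, adjusted p = 1.18e-05) and higher at 6pm (1.57, adjusted p = 5.88e-05), with -0.20 (adjusted p = 0.649) at 6am. As the mean of 4 times Nr1d1 was not called for ethanol (0.58, adjusted p = 0.0549 in wild type, 0.54, adjusted p = 0.0695 in the knockout-labelled arm) or for the knockout label in controls (-0.47, adjusted p = 0.111).

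A cosine fitted to the 11 clock genes that were rhythmic in every arm put the ethanol peaks a median of -5.6 h (range -6 to -3.2) from control in wild type and -2.7 h (-8.6 to -1.8) in the knockout-labelled arm, earlier in 11 of 11 genes in both. Arntl peaked at 5.3 ± 0.4 h (SE) of the clock in wild-type controls and at 23.5 ± 0.7 h with ethanol, and at 4.5 ± 0.3 and 1.8 ± 0.7 h in the knockout-labelled arm. Controls labelled knockout peaked a median of -0.7 h (-1.9 to -0.1) from wild type. The times were 6 h apart, so an hour is an extrapolation from 4 points, and the shifts were not tested between genotypes.

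**Figure D5:**
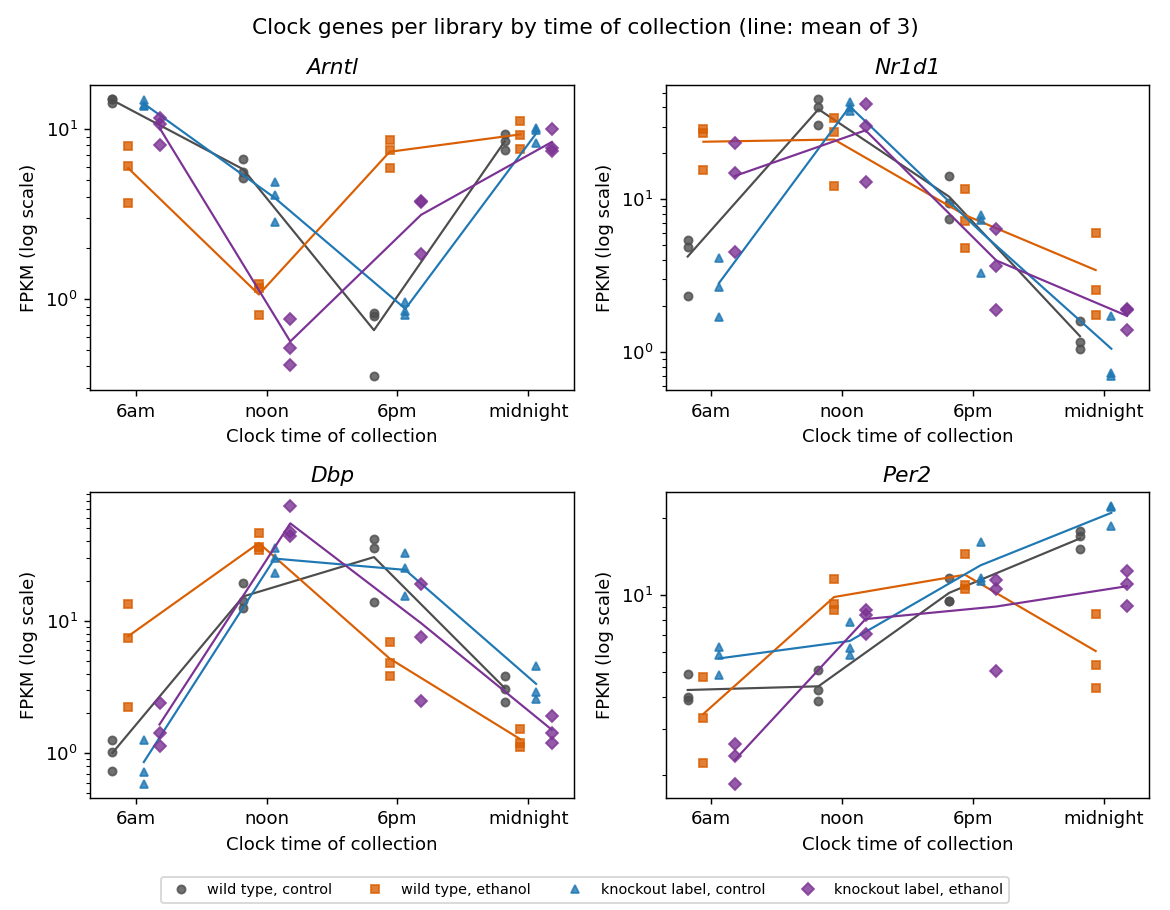
FPKM (log axis) of Arntl, Nr1d1, Dbp and Per2 in each library by clock time, coloured by genotype label and treatment, with lines through the means of 3 libraries. At 6pm Arntl has means of 0.65 FPKM in wild-type controls and 7.33 FPKM in wild-type ethanol livers.

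The ethanol effect depended on time in 1457 genes in wild type and 1506 in the knockout-labelled arm. The smallest adjusted p in wild type were those of Arntl (1.55e-11), Dtx4 (4.2e-08), the choline kinase Chka (2.83e-07), Cry1 (3.16e-07) and Npas2 (3.35e-07), and in the knockout-labelled arm those of Arntl (2.41e-06), Dtx4 (2.36e-05), the arginine transporter Slc7a1 (0.000196), Adh5 and Tef (both 0.000221). Of the 7 clock activators and 12 output genes, 5 and 8 were time-dependent in wild type (7 and 9 over the list alone), and 3 and 9 in the knockout-labelled arm (5 and 10 over the list alone), while Per1 was not (adjusted p = 0.406 and 0.358). None of the 6 Cyp4a genes was time-dependent in wild type, and in the knockout-labelled arm Cyp4a32 was (adjusted p = 0.0163). With only the libraries compared the counts were 2553 in wild type and 195 in the knockout-labelled arm, and without midnight control replicate 2 or noon control replicate 1 the latter was 687 or 896. The effect of the knockout label in controls depended on time in 9 genes (1072 at an unadjusted p under 0.05), led by Cox7c, D430001F17Rik and Brp44l (adjusted p = 0.0298) and Reep6 and mt-Ts2 (0.0307). Voom called 0 there, and for these 5 genes gave adjusted p from 0.0513 to 0.113. Their calls were lost in 6 (Brp44l) to 9 (mt-Ts2) of 24 fits that left out 1 library.

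At single times, ethanol changed 1653 genes at 6am (1011 higher, 642 lower), 1026 at noon (607, 419), 2533 at 6pm (1342, 1191) and 1329 at midnight (750, 579) in wild type. Library totals alone turned these splits to 551 and 823 at 6am, 275 and 785 at noon, 1721 and 602 at 6pm, and 1011 and 398 at midnight. In the knockout-labelled arm 1144 genes changed at 6am (654, 490), 3079 at noon (1745, 1334), 976 at 6pm (458, 518) and 1270 at midnight (542, 728). There library totals alone gave 183 and 1713 at 6am, 244 and 6224 at noon (median gene -0.385) and 145 and 2039 at 6pm. With only the libraries compared, limma called 52, 1884, 0 and 21 genes at these 4 times in the knockout-labelled arm, and 1036 at 6am, 1431 at 6pm and 2683 at midnight in wild type. Leaving out 1 library moved the wild-type counts to as few as 813, 421, 1483 and 586 at the 4 times, and those of the knockout-labelled arm to as few as 320, 1618, 386 and 472, with up to 2126 at midnight. At midnight the knockout-labelled arm had lower Nr0b2 with ethanol (-1.84, SE 0.51, adjusted p = 0.0208).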

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

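The tests of a transcript kept by the targeted allele, of scaling, of inflamed animals at 6pm, of all 8 libraries under the limit of the rank correlation and of acute phase genes by time or without single libraries were chosen only after the result was seen, as were the fits without 6pm and without the 4 libraries that stood apart. The remaining tests were set before their own results were seen, though the libraries that stood apart and the patterns themselves came from the same data.

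Nr0b2 was not called lower in libraries labelled knockout (-0.18 in controls, adjusted p = 0.626). Labels that do not follow the allele are argued against by the 25 genes that separated all 48 libraries by label: 13 of the 24 with a position lay within 20 Mb of Nr0b2, against 412 of 13258 other genes (odds ratio 36.8, 95% interval 15.1 to 91.4, Fisher's exact test, two-sided p = 5.58e-14). Fisher's test takes genes as independent, which neighbours such as the overlapping Tmem51 and Gm10565 are not, so this interval and p may be too narrow and too small. Over all libraries, control and ethanol, the mean Nr0b2 FPKM of those labelled knockout was 0.974 of wild type. Reads from a transcript kept by the targeted allele may account for this level. This cannot be told apart from an intact gene, because gene totals do not show which exons were read and the targeted part is not given in the sources used here. What the allele does to the SHP protein was not measured, so a loss of function stays open and untested.

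Acute phase genes rose with ethanol in the knockout-labelled arm, and the difference from wild type, whose medians went from 0.71 at 6am to -1.05 at 6pm, had a median of 1.2 (9 of 22 called, adjusted p = 0.556 for the arm and 0.54 for the difference with an estimated correlation). The 4 libraries that stood apart, each the lowest of its group, do not account for it as a set, since without them the median was 1.14 with 8 called. The highest liver, noon replicate 1 of the knockout-labelled ethanol arm (10.47), was not among them. Scaling by the library total does not account for it either, since size factors gave 1.21 and library totals alone 0.96. Without all 8 libraries under the limit only 6am and noon can be compared, where the median was 0.71 (1 called, camera adjusted p = 0.0414, adjusted p = 0.854 with an estimated correlation) against 0.82 with every library kept (0 called, camera adjusted p = 0.0265, adjusted p = 0.96 with an estimated correlation), so whether these 8 account for it stays undecided. Inflamed animals among the wild-type controls of 6pm could account for part of it, since over the other 3 times the median was 1.04 with 0 called (camera adjusted p = 2.62e-05, adjusted p = 0.798 with an estimated correlation), which leaves this undecided too, while fits without any single library, the high livers of noon and 6pm replicate 1 in the knockout-labelled ethanol arm (10.47 and 10.36) included, gave medians of 0.99 to 1.35 with 4 to 14 called. No fit left out the noon liver together with the high livers of 6pm, so whether a few such livers account for the difference stays undecided. An effect of genotype on the inflammatory response to ethanol, which the design names, stays open as a hypothesis.

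Clock genes of wild-type ethanol livers stood at other times of day than in controls, with a time-dependent ethanol effect in 13 of 19. An exchange of the wild-type ethanol libraries of 6am and 6pm is argued against, since with both sets exchanged 14 of 19 were called. This cannot decide on a shift of all wild-type ethanol time labels by the 6 h between times, which was not tested. The median peak shift was -5.6 h. The 6am library that stood apart is argued against as well, since without it 13 of 19 were called. An earlier clock in ethanol livers is consistent with these values, as a hypothesis found and tested on the same data. The hours at which the mice ate are not given in the sources used here, so an effect of feeding time is untested and stays open beside one of ethanol.

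Splits of the same libraries were drawn for every count, 100 for each result over several times, the real one included. Only 1 of 100 splits, the real one, gave as many calls for ethanol in wild type (4171, highest other 938) and in the knockout-labelled arm (4348, 1825). This was also so for the knockout label in controls (4457, 493) and in ethanol mice (3899, 1900). It was so too for time of day in wild-type controls (1150, highest other 466), wild-type ethanol livers (2791, 1395), controls labelled knockout (1755, 1064) and ethanol livers labelled knockout (5253, 3690, with a median of 592 over the other splits). For these counts chance is argued against, at 1 of 100, the smallest share that 100 splits can reach. This concerns each count as a whole and not its single genes. The time-of-day count of ethanol livers labelled knockout also fell when only the libraries compared were fitted, so the splits do not settle its size. The real split also gave the most calls for the difference (1102, highest other 317). The same held for time dependence of the ethanol effect in wild type (1457, 205) and in the knockout-labelled arm (1506, 932). The splits for the difference and for time dependence also broke up the effects of ethanol or of time themselves. They therefore cannot decide whether chance gave those calls. For the time dependence of the knockout effect in controls 5 of 100 splits gave at least the 9 real calls, with 465 as the highest other, so chance cannot be excluded. The cause of the high counts of some other splits, most of all in ethanol livers labelled knockout, was not tested.

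At single times 3 livers against 3 make 10 splits, too few for a share under 0.05. The real counts and the highest other were 1653 and 2 at 6am, 1026 and 1 at noon, 2533 and 2 at 6pm and 1329 and 1 at midnight in wild type. In the knockout-labelled arm they were 1144 and 75 at 6am, 3079 and 450 at noon, 976 and 1333 at 6pm (2 of 10 splits as large) and 1270 and 423 at midnight.

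Ethanol effects that differed between genotypes by the test of the difference (knockout-labelled minus wild type, log2) were 4.82 for Saa2, 4.37 for Saa1, 2.31 for Saa3, 3.14 for Mup7, 3.08 for Mup11, 3.07 for Mup17, 2.86 for Mup14, 2.32 for Mup1, 2.93 for Serpina4-ps1 and 2.88 for Hsd3b5. Further differences above 0 were 1.52 for Fabp5 (adjusted p = 0.00404), 1.46 for Cib3 (0.0131) and 0.82 for Cyp2e1 (0.00472). Differences below 0 were -3.29 for Cyp2a22, -3.12 for Gstm3, -2.62 for Cyp2b10, -2.43 for Cbr3, -2.38 for Cyp2c55, -2.19 for Gm10680, -2.17 for Apoa4, -2.08 for Gsta2, -1.95 for Slco1a4, -1.84 for Acot2 and -1.38 for Abcc4 (0.00788). These belong to the 1102 genes called for the difference. Some, such as Mup14 (-5.57) and Gstm3 (2.49), already differed by genotype label in controls, so starting level and response are not separated.

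Ethanol effects that differed between times of collection (also times since the binge) in wild type, among 1457 genes called, had adjusted p of 1.55e-11 for Arntl, 4.2e-08 for Dtx4, 2.83e-07 for Chka, 3.16e-07 for Cry1, 3.35e-07 for Npas2, 7.22e-06 for Dbp, 1.52e-05 for Per2, 0.000102 for Per3, 0.000288 for Clock, 0.00402 for Nr1d1, 0.00936 for Nr1d2 and 0.0226 for Cyp7a1. In the knockout-labelled arm, among 1506 genes, they were 2.41e-06 for Arntl, 2.36e-05 for Dtx4, 0.000196 for Slc7a1, 0.000221 for Adh5 and for Tef, 0.000875 for Cyp2e1, 0.00259 for Per2, 0.0059 for Dbp, 0.0163 for Cyp4a32, 0.023 for Nr1d1 and 0.0418 for Nr1d2. The effect of the knockout label in controls was called different between times in 9 genes, for which chance cannot be excluded. Cox7c, D430001F17Rik and Brp44l led at 0.0298, with Reep6 and mt-Ts2 at 0.0307. Taken alone, groups of 3 are too small for a test of single libraries far from their group. Such a test with the spread shared among all groups was not run.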

How the results depend on the processing

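Pseudocounts, voom, array weights, and the fits without the 4 libraries that stood apart and without 6pm were chosen only after the data were seen. Among the 254 results for named genes and the 170 list tests, no call reversed under any alternative. The joint tests of time of day and of time dependence among the 254 have no direction, so they could not reverse. Other called genes were not checked for this, and the naming rule favoured genes of the same sign at each time. The balance of higher and lower calls did change with library totals alone. Median-of-ratios size factors and both filters on low values moved no count by over 1.5 times and changed no call of the 254 results for named genes. The planned DESeq2 test was not run because the deposited values are FPKM. The recovered reads could have been used for it and for the planned main test, and voom was the only fit made on them. The fit of only the libraries compared keeps the same fold changes and alters only the estimate of spread and its degrees of freedom. Its lower counts in the knockout-labelled ethanol arm therefore show calls that rested on the spread shared with the other groups. The cause of the other moves was not tested, except that a left-out library leaves fewer samples.

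Library totals alone called 7301 genes for ethanol in the knockout-labelled arm, 3828 for the difference, 2343 for time dependence in that arm, and 1896 at 6am, 6468 at noon and 2184 at 6pm there. With only the libraries compared, limma called 1107 for time of day in controls labelled knockout and 229 in ethanol livers labelled knockout. For time dependence of the ethanol effect it called 2553 in wild type and 195 in the knockout-labelled arm. For ethanol in wild type it called 1036 at 6am, 1431 at 6pm and 2683 at midnight, and in the knockout-labelled arm 52 at 6am, 1884 at noon, 0 at 6pm and 21 at midnight.

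Array weights called 2842 for the difference, 3213, 6331 and 4407 for time of day in wild-type controls, wild-type ethanol livers and controls labelled knockout, and 4448, 4602 and 487 for time dependence of ethanol in wild type, of ethanol in the knockout-labelled arm and of the knockout label. For ethanol at single times they called 3554 at 6am, 2700 at noon and 4116 at midnight in wild type, and 5892 at noon and 4078 at midnight in the knockout-labelled arm. Without the 4 libraries that stood apart the counts were 1717 for the difference, 2227 for time of day in wild-type controls and 2912, 2888 and 86 for the 3 tests of time dependence. At single times they were 1920 at noon and 2340 at midnight in wild type, and 2116 at 6am, 547 at 6pm and 2998 at midnight in the knockout-labelled arm. Without 6pm the difference called 602. Voom called 0 for the time dependence of the knockout effect, where limma-trend called 9 and 1072 had an unadjusted p under 0.05.

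Leaving out each library in turn moved none of the 5 counts over 4 times beyond 1.5 times. Where counts moved, they ranged from 715 to 1084, 1669 to 2886 and 819 to 1840 for time of day in wild-type controls, wild-type ethanol livers and controls labelled knockout, from 687 to 1901 for time dependence of ethanol in the knockout-labelled arm and from 0 to 20 for that of the knockout label. For ethanol at 6am, noon, 6pm and midnight they ranged from 813 to 1619, 421 to 732, 1483 to 2226 and 586 to 850 in wild type, and from 320 to 1251, 1618 to 3355, 386 to 1197 and 472 to 2126 in the knockout-labelled arm.

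Of 47 list calls 1 held with an estimated correlation. Replicate numbers were not taken to pair the libraries (mean correlation of deviations -0.002 for shared numbers against 0.001 for others). Of 48 libraries 23 correlated best with their own number, against a median of 17 (8 to 31) in 99 permutations of the numbers within groups, of which 13 gave at least as many. The replicate block moved no count by over 1.5 times, ended the call of Ppara in wild type (adjusted p = 0.0512) and made 1 list call. Among the named results, library totals alone ended 3 calls and made 9, the fit of the libraries compared 14 and 6, voom 15 and 0, array weights 1 and 16, the fit without the 4 libraries 2 and 13, the fit without 6pm 8 and 11, and pseudocounts of 0.1 and 1 ended 1 call each and made 1 and 0. Of the list calls, fry ended 8 and made 3. Genes under 0.5 FPKM, where 1 read is worth 0.051 to 0.104 FPKM in 1000 bases, are limited by depth.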

Other observations

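The test of gene copies was chosen only after the result was seen. Lists that were called in none of the 5 comparisons held single genes that changed. Of 14 genes of ethanol and acetaldehyde metabolism, 2 rose and 4 fell with ethanol in both genotypes (camera adjusted p = 0.667 in wild type and 0.541 in the knockout-labelled arm). Acss2, which makes acetyl-CoA from acetate, fell by 1.45 and by 1.33, and the alcohol dehydrogenase Adh4 fell by 0.73 and by 0.59. Aldh1a1 rose by 0.82 in wild type. In controls labelled knockout Aldh1b1 was higher (0.93) and Acss3 lower (-0.94). Of 21 one-carbon and methionine genes, 3 rose and 3 fell in wild type (camera adjusted p = 0.931), with Mat1a, which makes S-adenosylmethionine in liver, at 0.76 and the methionine synthase Mtr at -0.47, and 5 rose and 2 fell in the knockout-labelled arm (0.827), with 0.81 and -0.72 for the same genes. Of 14 lipid droplet genes, 2 were higher and 5 lower in ethanol livers labelled knockout than in wild type (camera adjusted p = 0.0712), with Fitm1 at -1.69 and the fatty acid transporter Cd36 at -0.71.

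Of 17 bile acid transport and FXR genes, 5 were higher and 6 lower in controls labelled knockout than in wild type (camera adjusted p = 0.703), with the basolateral exporter Ostb at 1.69, the phospholipid pump Abcb4 at 0.67, the receptor FXR (Nr1h4) at -0.38 and Slco1b2 at -0.47. Abcc3 rose with ethanol by 1.35 in wild type and by 0.66 in the knockout-labelled arm. Of 13 immediate early genes, 3 rose and 2 fell with ethanol in wild type (0.968), with Egr1 at 1.51 and Dusp1 at -1.93. Among 5 fat tissue markers, Cfd had a difference of 3.40 between the ethanol effects (adjusted p = 0.002), with -2.24 in wild type and 1.16 (adjusted p = 0.0617) in the knockout-labelled arm, and the list was not called (0.058). Of 9 cholangiocyte markers 1 was higher in controls labelled knockout (0.417), Tspan8 at 0.92. The 7 clock activators and 12 clock output genes were not called as lists in any of the 5 comparisons of 4-time means (lowest camera adjusted p 0.173 and 0.232).

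Copies of other genes were among those that separated the libraries by genotype label. A strain variant near Nr0b2 that moves reads between a gene and its copy elsewhere is a candidate explanation. Among 207 gene copies that lie outside 20 Mb of Nr0b2 and have a parent (at least 90% identity over at least 50% of the copy), the 3 that separated the labels had 3 different parents, all within 20 Mb of Nr0b2. Of the 195 other parents, each counted once, 3 lay there, and the lower 95% bound of the odds ratio was 17.1 (Fisher's exact test, p = 1.57e-05). The test took neighbouring parents as independent, so this bound and p may be too extreme. The copies were Gm10036 (chromosome 18, 99.3% identical to Rpl11), Gm5506 (chromosome 18, 99.5%, Eno1) and BC002163 (chromosome 16, 99.4%, Ndufs5). Another separating copy, Gm12901 (chromosome 4, 90.8%, Rpl11), itself lies within this distance and was left out of the test. Their log2 changes in controls were 3.62, 3.87, 4.16 and 3.20, where Rpl11, Eno1 and Ndufs5 had -0.28, -1.49 and -3.54. The values suggest flanking sequence of another strain around the targeted allele, a hypothesis that gene totals cannot test further, and the strain in which the allele was made is not given in the sources used here.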
